A study of Mus musculus with 49 samples.

How the data were processed

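RNA of 49 CT26 tumours was sequenced as QuantSeq 3′ FWD libraries, a stranded kit that reads the 3′ end of each transcript, per the labels' protocols. The deposited count table holds raw counts per Ensembl gene (unit: counts) for 39179 genes, of which 37607 could be given a symbol. Per the submitters' processing notes, the authors used bcl2fastq, STAR, featureCounts and limma with the builds mm10 and GRCm38. Tool versions, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited second table holds log2 values per gene (unit: log2 CPM) for 16559 genes. It was checked against the counts: in each library the value equals log2 of the count plus 0.5 over 1 constant, with a largest spread of 9.99e-09, and that constant matched the TMM effective library size to 3.89e-05 of its value. The filter behind it is not given in the sources used here, and the tests used the counts. Gene symbols and coordinates came from the mouse annotation on GRCm38.

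Total counts per library ranged from 4251251 to 13671294 (median 7670623). The medians were 8730438 with vehicle, 6491315 with celecoxib, 8524806 with anti-PD-1 and 7531651 with the combination. The intervals printed for shares of tumours cover the number of tumours, and standard errors come from the spread between tumours. The most alike pair of libraries had a Pearson r of 0.983 between log2 CPM and a chi-square of 17.7 per gene, so no library was a copy of another.

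Groups came from the labels. Replicate numbers only name the tumours in the order of the labels. Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr, robust quasi-likelihood fits and the Benjamini-Hochberg adjustment, with 0.05 as the limit on the adjusted p. The 4 treatments were compared in 1 fit of all libraries (13726 genes), and the R and NR comparisons in 1 fit of 6 groups (14247 genes). Interactions were contrasts of the same fits. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 37 of 38 fixed lists with at least 4 tested genes. Eosinophils had 2 tested genes and were not tested. Some tested lists kept few of their fixed genes in the fit of the 4 treatments. These were 4 of 19 for skin epithelium, 4 of 13 for plasma cells, 5 of 14 for B cells and 7 of 13 for mitochondrially encoded transcripts. Shares were compared with Fisher's exact test. List means per tumour and correlations were compared by permutation in Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6, exact where a group had fewer than 10 tumours and otherwise with 100000 resamples, two-sided. For the 9 vehicle tumours the correlation was planned with resampling and computed exactly.

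The gene lists, the comparisons, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, up to 8 higher and 8 lower genes with the largest fold change among those past the limit with a mean of at least 2 CPM, leaving out predicted genes and antigen receptor segments. It adds the 3 members with the smallest p of each list that passes camera, summarised in the text where there are many, and a fixed panel of 18 genes. The values of some genes that the rule names are not reported here. The clock genes beyond those called, the clock measure and the limits that define libraries with other tissue were chosen after the data were examined.

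The pipeline was tested on simulated data made from the libraries' own spread per gene. Genes were drawn independently, without the correlation between genes of the real tumours. False calls in the real data can therefore exceed the counts given here, and recovery can be lower than the shares given here. For the combination against anti-PD-1 edgeR recovered 79% of genes changed by 1 log2 unit and 99% of those changed by 2, with 12 unchanged genes called. For R against NR under anti-PD-1 it recovered 51% and 79%, with 6 unchanged genes called. DESeq2 1.42.0 recovered 80% and 100% in the first setting, and 55% and 84% in the second.

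Alternatives tried were DESeq2, limma-voom, RLE normalization, no filter on low counts, fits of the compared groups alone, the muscle list as a covariate, an estimated correlation, fry, z-scored list means, regression of the correlated lists on muscle, Barnard's exact test, and leaving out libraries of the groups of 4. Added later were leaving out each library of the 4 treatments in turn, removal of 12 libraries with a muscle list mean over 3 or a skin or adipocyte list mean over 5, the clock measure as a covariate, permutation of list means, and differences of the means of called lists without each library of the groups compared. No library was left out of the values in the report.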

Results

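The data are 49 libraries of CT26 tumours, a mouse colorectal carcinoma line grown in BALB/c mice. Vehicle was given to 9 tumours, celecoxib (an inhibitor of the prostaglandin-producing enzyme COX-2, encoded by Ptgs2) to 7, an antibody against the T cell inhibitory receptor PD-1 to 17, and both to 16. Per the labels, treatment started on day 7 after injection and lasted 7 days, with celecoxib at 30 mg/kg daily and anti-PD-1 at 200 µg per dose in 2 doses. The tissue label places the tumours on day 7 of treatment, whereas the extraction protocol gives day 4, and the sources used here do not settle which is right. Each tumour carries a response label R or NR, which the labels do not define, and all vehicle and celecoxib tumours are NR. The labels do not state that every tumour came from a different animal, so the p-values measure the spread between these samples. Coordinates are on GRCm38. Fold changes are log2 from edgeR with their standard error (SE), and group values are mean CPM (counts scaled to the library size) ± SD.

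The question behind the design is whether blocking COX-2 changes the tumour response to anti-PD-1. In the combination group 12 of 16 tumours were labelled R (75%, 95% Clopper-Pearson interval 47.6 to 92.7%), against 4 of 17 with anti-PD-1 alone (23.5%, 6.81 to 49.9%). The odds ratio was 9.75 (two-sided Fisher's exact test, p = 0.00527). Only profiled tumours are counted.

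With celecoxib alone, the means of Ptgs2 and of the prostaglandin pathway list differed from vehicle by less than the SD of the vehicle tumours. Ptgs2 (chromosome 1, 150100031 to 150108227) measured 13.5 ± 8.19 CPM in 7 celecoxib tumours and 16.8 ± 16.7 CPM in 9 vehicle tumours, a log2 change of -0.32 (SE 0.63). Vehicle replicate 8 stood apart at 5.95 log2(CPM + 1), with the next vehicle tumour at 4.12, so the vehicle mean of Ptgs2 leans on that tumour. The mean of the prostaglandin pathway list was 3.62 ± 0.20 log2 CPM with celecoxib and 3.62 ± 0.23 with vehicle (exact permutation p = 0.963). Among the tumour-promoting inflammation genes, Cxcl2, a neutrophil-attracting chemokine, differed by -1.10 (SE 0.66) and Arg1, the arginine-degrading enzyme of myeloid cells, by -1.003 (SE 0.47), neither past the adjusted threshold. The mean of that list was 3.15 ± 0.40 against 3.45 ± 0.32 log2 CPM (exact permutation p = 0.111, adjusted p 0.997).

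In this comparison edgeR called 0 of 13726 genes, with 314 at an unadjusted p under 0.05. Limma-voom called 0, DESeq2 7 and edgeR without a filter on low counts 49. Camera with the preset correlation called 8 lists, none of which held with an estimated correlation between genes (adjusted p from 0.67 for the muscle, skin and mitochondrial lists to 0.971 for endothelium). The largest shift was in the skeletal muscle list (23 of 23 members positive, median 4.86; 22 rose when adjusted over the list alone, 0 over all genes), where Pygm, Neb and Mylpf, which encode muscle phosphorylase, nebulin and a myosin light chain, gave 4.51, 4.72 and 5.03. This content was uneven: celecoxib replicates 1 and 3 had list means of 7.35 and 6.70 log2 CPM. The skin epithelium list, with 4 of its 19 genes tested, was highest in celecoxib replicate 3, at 6.52. Its median change was 1.82, with Krt10 at 2.31 and Sbsn at 2.65, and 2 rose when adjusted over the list alone. The adipocytes list was called down (10 of 10 negative, median -2.23; 5 fell when adjusted over the list alone), led by Thrsp, Retn and Adipoq, and vehicle replicate 6 held its highest mean, 6.56. All 24 tested hypoxia and glycolysis genes were negative (median -0.61, camera adjusted p 1.85e-05), among them Gapdh at -1.18 (SE 0.59), with vehicle replicate 8 standing apart on this list at 8.29 log2 CPM (next vehicle tumour 6.64). The type I interferon list had 23 of 26 members positive (median 0.31) with Xaf1 at 0.70, and the mitochondrially encoded list had 7 of 7 positive (median 0.34). For pericytes the median was -0.02 while the mean, 0.21, and the camera direction were positive; endothelium had a median of 0.10.

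Differences of list means per tumour, computed without each library after the data were seen, moved by over 1.5 times for 7 of these 8 lists. Without vehicle replicate 8, hypoxia went from -0.44 to -0.18, type I interferon from 0.28 to 0.14, pericytes from 0.34 to 0.13 and endothelium from 0.18 to -0.01. That tumour had means of 5.15 for type I interferon and 1.69 for endothelium (next for endothelium 2.97). Muscle went from 1.75 to 0.86 and 0.97 without celecoxib replicates 1 and 3, skin from 0.51 to -0.08 without celecoxib replicate 3, and adipocytes from -0.61 to -0.07 without vehicle replicate 6. Type I interferon also moved without celecoxib replicate 4 (0.17), and endothelium without vehicle replicate 1 (0.28) or celecoxib replicate 2 (0.07).

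Dbp had the smallest adjusted p between anti-PD-1 alone and vehicle. Dbp (chromosome 7, 45705088 to 45710203), a clock-controlled transcription factor, fell by 2.60 on the log2 scale (SE 0.30, adjusted p 2.13e-07), from 98.8 ± 47.02 CPM in 9 vehicle tumours to 16.4 ± 11.3 CPM in 17 anti-PD-1 tumours. Arntl (chromosome 7, 113207465 to 113314126), which encodes the activator BMAL1 and peaks in the opposite phase, rose by 1.26 (SE 0.22), from 8.14 ± 3.32 to 19.5 ± 6.27 CPM. The repressors Per2 (-1.79, SE 0.23) and Per3 (-1.45, SE 0.17), the Dbp relative Tef (-1.64, SE 0.20), the nuclear receptor Nr1d2 (-0.90, SE 0.13) and the repressor Cry2 (-0.86, SE 0.18) fell as well. Other genes known to follow the circadian clock did not pass: Hlf (-1.13), Per1 (-1.11), Ciart (-0.78), Nr1d1 (-0.68), Bhlhe41 (-0.57), Clock (0.44) and Nfil3 (0.74). These were picked after the data were seen and were not tested as a list. The labels give no collection time.

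In all, 2 genes rose and 10 fell of 13726, with 478 at an unadjusted p under 0.05; DESeq2 called 22 and edgeR without a filter on low counts 24, and 0 with the clock covariate, which is built from these genes. Besides those above, the glucocorticoid-induced Tsc22d3 (-1.10, SE 0.22) and Fkbp5 (-0.83, SE 0.14) fell, as did the ER flavoprotein gene Foxred2 (-1.29) and the chloride channel regulator gene Clca3a1 (-0.72). The matrix gene Spon2 rose by 1.24 (SE 0.21). Leaving out 1 library at a time gave 8 to 17 calls, and Arntl, Dbp, Fkbp5, Nr1d2, Per2, Per3, Spon2 and Tef were called in all 26 such fits. The combined clock measure (mean log2 CPM of Dbp, Tef, Per2, Per3 and Nr1d2 minus that of Arntl), chosen after the data were examined, was 3.62 ± 0.48 with vehicle, 3.74 ± 0.42 with celecoxib, 0.65 ± 0.62 with anti-PD-1 and 3.12 ± 0.98 with the combination. Cry1, which also moves with Arntl's phase in part, went the other way (-0.84, SE 0.20, adjusted p 0.089).

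**Figure D1:**
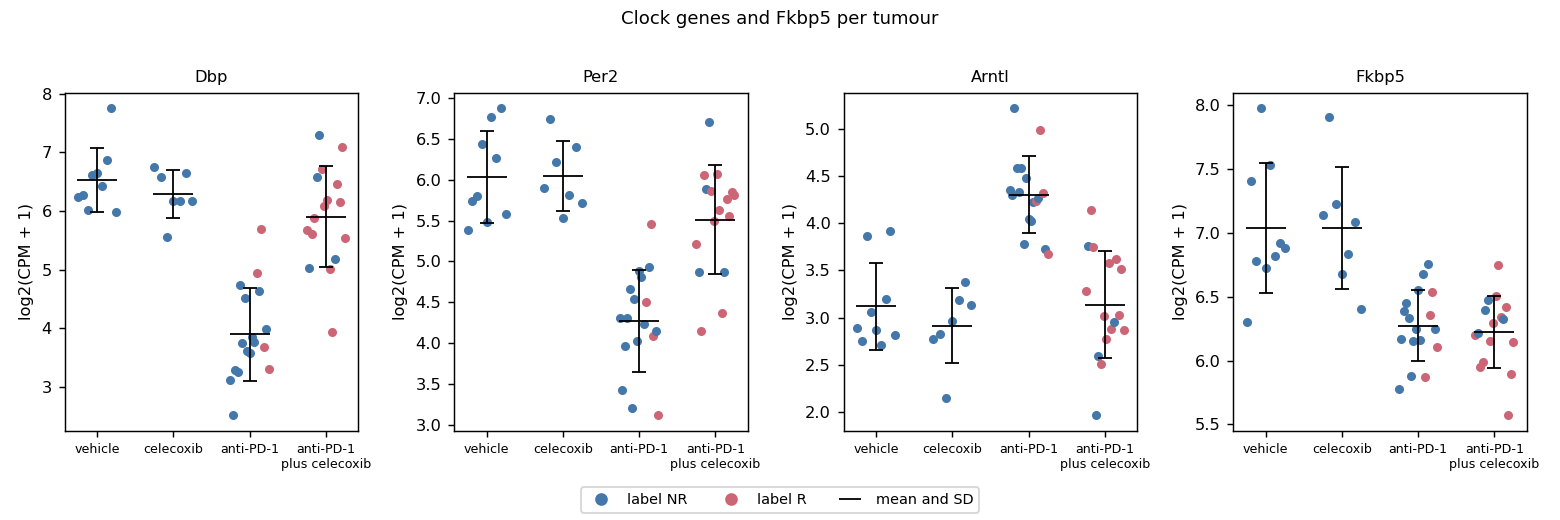
Each point is a tumour, coloured by response label, with log2(CPM + 1) of Dbp, Per2, Arntl and Fkbp5 on the vertical axes and the treatment groups along the horizontal axes; bars are mean and SD. Mean Dbp was 16.4 CPM with anti-PD-1 against 98.8 with vehicle and 68.9 with the combination.

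No immune gene of the panel passed between anti-PD-1 and vehicle tumours. Cd8a, the co-receptor of cytotoxic T cells, differed by -0.48 (SE 0.74), Gzmb, a cytotoxic granule protease, by 0.12 (SE 0.53), and Ifng by 0.50 (SE 0.68). Camera called 18 lists, 12 up and 6 down, none of which held with an estimated correlation (adjusted p 0.115 for endothelium, pericytes and mitochondrially encoded transcripts, 0.322 to 0.665 for the others). Endothelium was positive in 18 of 18 members (median 0.51), with the vessel receptor Robo4 at 0.66. Pericytes were positive in 9 of 9 (median 0.40), with Abcc9 at 1.08 and Rgs5 at 0.89; 3 rose when adjusted over the list alone and 0 over all genes. The mitochondrially encoded (median 0.40), fibroblast (0.19), unfolded protein (0.17), type I interferon (0.21), NF-kB (0.14), mature dendritic (0.23), other conventional dendritic (0.37), red blood cell (0.83), muscle (1.90) and tumour-promoting inflammation (0.22) lists were also up; NF-kB had 2 members rising when adjusted over the list alone, and mature dendritic cells and inflammation 1 each. Down were hypoxia and glycolysis (0 of 24 positive, median -0.34), mast cells (-0.32), T cells (-0.13), inhibitory receptors (-0.30), cytotoxic lymphocytes (-0.10) and NK cells. The NK cell call was down on a positive median of 0.03 and a negative mean of -0.09.

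Of these 18 differences of list means, 12 moved by over 1.5 times without 1 library. Without vehicle replicate 8 (hypoxia 8.29, next 6.64), endothelium went from 0.51 to 0.32, pericytes from 0.59 to 0.38, hypoxia from -0.37 to -0.11, type I interferon from 0.16 to 0.03, NF-kB from 0.13 to 0.06 and mature dendritic cells from 0.17 to 0.06. T cells went from -0.37 to -0.55 and NK cells from -0.38 to -0.61 without it. Without anti-PD-1 replicate 14, T cells and NK cells were both at -0.21, mast cells went from -0.56 to -0.36, cytotoxic lymphocytes from -0.49 to -0.31, and type I interferon was at 0.27. Without vehicle replicate 5, fibroblasts went from 0.21 to 0.13, inflammation from 0.15 to 0.09 and T cells to -0.22. Type I interferon was 0.10 and 0.09 without anti-PD-1 replicates 2 and 17, and NF-kB 0.08 without replicate 2.

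The combination differed from vehicle in Fkbp5 and a mitochondrial transcript. Fkbp5 (chromosome 17, 28399094 to 28517527), a glucocorticoid receptor co-chaperone, fell by 0.88 (SE 0.15, adjusted p 0.0022), from 138 ± 53.4 to 75.1 ± 14.3 CPM (n = 9 and 16, edgeR). The gene was also lower with anti-PD-1 alone (77.7 ± 15.0 CPM), and both tests share the vehicle tumours. Mt-Nd5, a subunit of respiratory complex I, rose by 1.24 (SE 0.21), from 331 ± 61.8 to 783 ± 313 CPM. Pla2g4a (chromosome 1, 149829618 to 149961290), which encodes the phospholipase that releases arachidonic acid for prostaglandin synthesis, rose by 0.65 (SE 0.14), from 33.3 ± 4.62 to 52.1 ± 11.2 CPM.

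In this comparison 6 genes rose, 4 fell and 2110 had an unadjusted p under 0.05. The count of 10 depended strongly on the setting: it was 787 (437 higher, 350 lower) without the libraries with other tissue, 63 with the muscle list as covariate, 67 with DESeq2, 3 with limma-voom, and 2 with the compared groups alone or the clock covariate. Also higher were Atxn1 (0.58), Rap2b (0.52) and Btaf1 (0.48), a transcriptional repressor, a small GTPase and a TATA-binding protein regulator, and Bend4 (1.22), below the expression minimum for named genes and named because the count is small. Lower were the mismatch repair gene Msh6 (-0.51), the adaptor gene Apbb2 (-0.41) and the prolactin receptor gene Prlr (-5.76, SE 1.22), whose vehicle mean of 18.7 ± 53.6 CPM rests on vehicle replicate 6, the tumour with the highest adipocyte list. The count depended on single libraries. It was 2 to 5 without any one of the 9 vehicle tumours or of combination replicates 1, 2, 4, 6, 8, 9, 10, 11, 13, 14 and 16, but 16 without combination replicate 7, 44 without replicate 3 and 157 without replicate 15; Fkbp5 and mt-Nd5 were called in every such fit.

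The interferon-gamma response list had 34 of 34 members positive (median 0.74, camera adjusted p 3.12e-06), with Socs1, the feedback inhibitor of cytokine signalling, at 1.22 (SE 0.31) and Cd274, encoding PD-L1, at 1.60 (SE 0.43, adjusted p 0.129). Its call was lost with an estimated correlation (adjusted p 0.699), and 4 members rose when adjusted over the list alone, 0 over all genes. Without combination replicate 15, 2 members of the interferon-gamma, T cell and cytotoxic lists together passed over all genes. The mitochondrially encoded list (7 of 7 positive, median 0.74; 4 rising when adjusted over the list alone, 1 over all genes) had an estimated-correlation adjusted p of 0.0808 and passed fry at 0.00241. Its mean per tumour was 10.17 ± 0.44 against 9.46 ± 0.33 log2 CPM, higher than the vehicle median in 14 of 16 tumours (exact permutation p = 0.000468, adjusted p 0.0173). Cytotoxic lymphocytes (19 of 19, median 1.06, Prf1 at 1.88), T cells (20 of 20, 0.82), MHC class II (10 of 10, 0.74, 4 rising when adjusted over the list alone), macrophages (0.54), regulatory T cells (0.57), NF-kB targets (0.40, 3 rising when adjusted over the list alone), type I interferon (0.35), endothelium (0.17) and muscle (3.44, 21 rising when adjusted over the list alone) were up. Hypoxia (-0.57), cholesterol synthesis (-0.22) and proliferation (-0.14) were down. For all of these the estimated-correlation adjusted p was 0.699. Without vehicle replicate 8 (macrophages 5.09, next 6.33), differences of list means went from 0.43 to 0.24 for macrophages, 0.29 to 0.16 for type I interferon, 0.53 to 0.35 for T cells, 0.40 to 0.26 for regulatory T cells, 0.24 to 0.04 for endothelium and -0.45 to -0.20 for hypoxia. Proliferation went from -0.17 to -0.07 without combination replicate 14.

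Dbp also had the smallest adjusted p between the combination and anti-PD-1 alone. Dbp rose by 2.08 (SE 0.27, adjusted p 6.42e-06), to 68.9 ± 38.8 CPM in 16 combination tumours from 16.4 ± 11.3 in 17 anti-PD-1 tumours, with Per2 (1.29), Tef (1.27), Per3 (0.94) and Nr1d2 (0.65) higher and Arntl lower (-1.21, SE 0.18). Per1 (0.83), Hlf (0.79), Nfil3 (-0.61), Nr1d1 (0.55), Bhlhe41 (0.46), Ciart (0.45), Cry2 (0.35), Cry1 (0.34) and Clock (0.10) did not pass. Among the other called genes, Ccl4, a chemokine that attracts T cells and monocytes, rose by 1.67 (SE 0.40), Adora2a, the adenosine receptor that restrains T cells, by 1.45 (SE 0.35), and Cd180 and Ly86, which form a B cell and myeloid receptor complex, by 1.34 (SE 0.32) and 1.30 (SE 0.30). Nrgn, a calmodulin-binding protein gene, rose by 1.91. Among the 23 genes that fell were the matrix gene Spon2 (-1.09), the transcription factor gene Foxs1 (-1.07), the vessel receptor gene Robo4 (-0.91, SE 0.21), the lipase inhibitor Angptl4 (-0.89, SE 0.16) and the proteases Mmp3 (-0.86) and Adam12 (-0.79), with Mum1l1 (-0.83). Pla2g4a rose by 0.50 (SE 0.11), from 36.9 ± 9.31 to 52.1 ± 11.2 CPM, while Ptgs2 differed by 0.19 (SE 0.43).

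Of 13726 genes, 46 rose and 23 fell, with 2359 at an unadjusted p under 0.05. DESeq2 called 297 and limma-voom 33, and edgeR 153 with the muscle covariate, 22 without a filter, 19 with the compared groups alone, 11 without the libraries with other tissue and 0 with the clock covariate. The count of 69 rested on single libraries: it was 449 and 220 without combination replicates 15 and 3, and 214, 212 and 111 without anti-PD-1 replicates 1, 2 and 12. It was 13, 17, 21, 24, 26 and 26 without combination replicates 16, 4, 9, 11, 14 and 1. Without anti-PD-1 replicates 8, 5, 3, 15, 16, 4, 9, 13, 14 and 7 it was 16, 16, 18, 21, 23, 23, 25, 34, 42 and 42. Called in all 33 such fits were 13 genes: Dbp, Per2, Per3, Tef, Nr1d2, Arntl, Spon2, Foxs1, Angptl4, Adamts4, Pgap1, Polg and Ptprj.

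Camera called the interferon-gamma, cytotoxic and T cell lists up in the combination, and with an estimated correlation the adjusted p of each was 0.489. The interferon-gamma list had 34 of 34 members positive (median 0.60, 8 rising when adjusted over the list alone), with Cd274 at 1.27 (SE 0.34, adjusted p 0.0656) and Socs1 at 0.94 (SE 0.25). Cytotoxic lymphocytes had 19 of 19 positive (median 1.13, 13 rising when adjusted over the list alone), with Tbx21, the T-bet transcription factor, at 1.44 (SE 0.39) and Prf1, perforin, at 1.90 (SE 0.54, adjusted p 0.0755). T cells had 20 of 20 positive (median 1.04, 13 rising when adjusted over the list alone), with Cd3e at 1.47. Over all genes 0 members of these 3 lists passed in edgeR, a count that moved with single libraries. It was 13 without anti-PD-1 replicate 2 or combination replicate 15, 6 without anti-PD-1 replicate 1 or combination replicate 3, 3 without combination replicate 6 or 10, 2 without anti-PD-1 replicate 12 or 17, and 1 without anti-PD-1 replicate 11 or combination replicate 2 or 12. Per tumour, the cytotoxic list averaged 3.63 ± 1.495 against 2.45 ± 1.37 log2 CPM, with 14 of 16 combination tumours above the anti-PD-1 median (permutation p = 0.0241, adjusted p 0.192). The groups also differ in their R tumours, 12 of 16 against 4 of 17. Among NR tumours alone, with 4 in the combination, these lists were not called: cytotoxic lymphocytes had 7 of 19 positive (median -0.07, camera adjusted p 0.493), T cells 6 of 20 (-0.20, 0.651) and interferon-gamma 21 of 34 (0.09, 0.391). Among R tumours, with 4 under anti-PD-1, camera called all of them up. Cytotoxic lymphocytes had 19 of 19 positive (median 1.33), T cells 20 of 20 (1.36) and interferon-gamma 29 of 34 (0.34). None held with an estimated correlation (adjusted p 0.357 to 0.468), and their differences of list means shrank or turned without anti-PD-1 replicate 14.

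Camera's 13 up and 5 down lists became 0 with an estimated correlation (adjusted p 0.489 to 0.688). MHC class II (median 0.81, 5 rising when adjusted over the list alone), NK cells (0.79, 2), MHC class I (0.42, 3), mast cells (0.63, 3), type 1 dendritic cells (0.46, 0), inhibitory receptors (0.96, 2), NF-kB targets (0.23, 5), macrophages (0.44, 0), mitochondrially encoded transcripts (0.48, 2) and regulatory T cells (0.50, 3 rising and 1 falling) were also up, where the second number in brackets is the count of members rising when adjusted over the list alone. Down were fibroblasts (median -0.32, Col5a1 at -0.38), pericytes (-0.59, 5 falling when adjusted over the list alone), proliferation (-0.16), endothelium (-0.25, 1 falling) and cholesterol synthesis (-0.17). Without combination replicate 14 the differences of list means went from -0.17 to -0.07 for proliferation and from -0.15 to -0.07 for cholesterol synthesis.

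**Figure D2:**
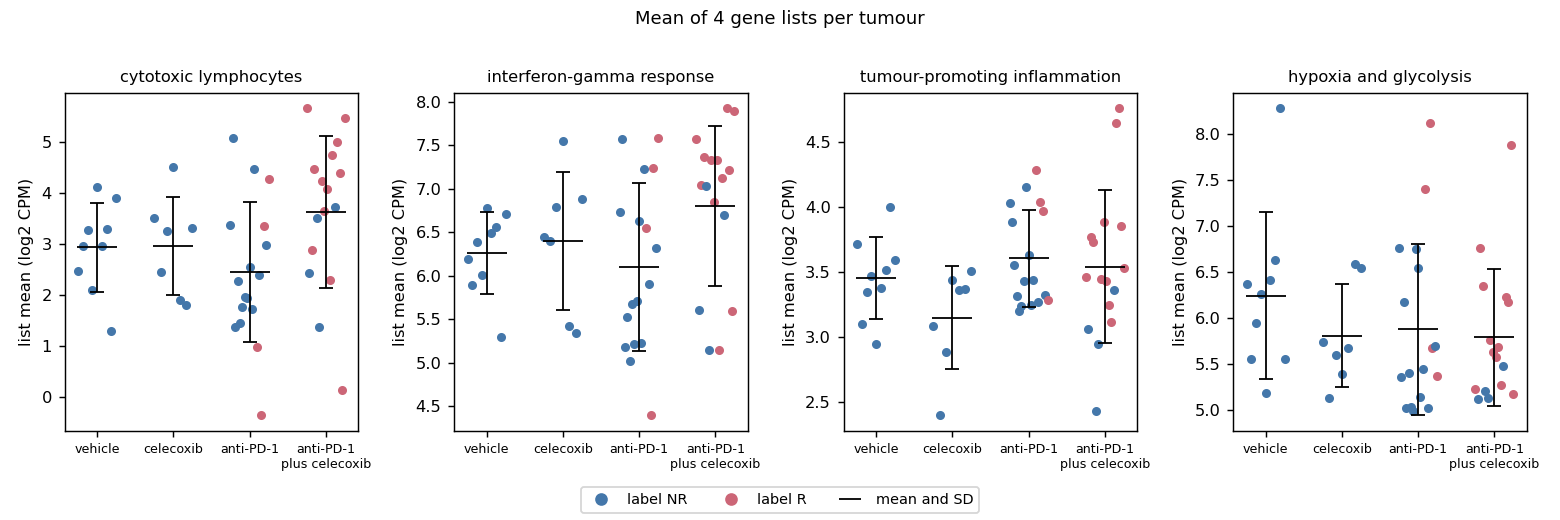
Each point is a tumour, coloured by response label, with the mean log2 CPM of the cytotoxic lymphocyte, interferon-gamma, tumour-promoting inflammation and hypoxia lists on the vertical axes and treatment groups along the horizontal axes; bars are mean and SD. The cytotoxic list averaged 3.63 with the combination and 2.45 with anti-PD-1, with overlapping tumours.

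Against celecoxib alone, Fkbp5 was lower in the combination (-0.87, SE 0.16, edgeR adjusted p 0.00824), from 137 ± 50.2 to 75.1 ± 14.3 CPM. Also called were Krt10 (-2.28), Sbsn (-2.84) and Dsp (-4.70), which encode skin keratin, suprabasin and desmoplakin, and the small nuclear RNA Rnu11 (-3.01). The direction of Sbsn and Dsp reversed with DESeq2, and that of Sbsn also without the libraries with other tissue. The 3 skin genes were high in celecoxib replicate 3 with its skin list of 6.52 log2 CPM. Without that tumour edgeR called 0 genes, and without celecoxib replicate 2 it called 3. In total 0 rose, 5 fell and 675 had an unadjusted p under 0.05. Without a filter edgeR called 124, with the muscle covariate 2, with the compared groups alone 1, and without the libraries with other tissue or with the clock covariate 0; limma-voom called 0 and DESeq2 2.

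Camera called 17 lists against celecoxib, none of which held with an estimated correlation (adjusted p 0.307 to 0.575). Those up were T cells (20 of 20 positive, median 0.87), cytotoxic lymphocytes (19 of 19, 1.01, Gzmk at 1.87), interferon-gamma response (34 of 34, 0.42), MHC class II (0.78), MHC class I (0.31), regulatory T cells (0.58), inhibitory receptors (0.72), macrophages (0.42), mast cells (0.67), NF-kB targets (0.34, 3 rising when adjusted over the list alone), mitochondrially encoded transcripts (0.58, 2), tumour-promoting inflammation (0.60, 1), cAMP targets (0.22, 1) and adipocytes (0.66). Cxcl1, a neutrophil chemokine, stood at 1.30 (SE 0.42, adjusted p 0.834). Cholesterol synthesis (1 of 18 positive, median -0.30, 2 falling when adjusted over the list alone), proliferation (-0.19) and skin (-2.23, 3 falling when adjusted over the list alone and 2 over all genes) were down. Differences of list means went from -0.66 to -0.07 for skin without celecoxib replicate 3, and for interferon-gamma from 0.40 to 0.24 and 0.22 without celecoxib replicates 5 and 6. Without celecoxib replicate 6, macrophages went from 0.28 to 0.18 and MHC class I from 0.26 to 0.15, the latter also moving without celecoxib replicate 4 (0.40) or combination replicate 13 (0.17). Proliferation went from -0.22 to -0.12 without combination replicate 14, and mast cells from 0.42 to 0.66 without replicate 15.

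Whether celecoxib acted differently with and without anti-PD-1 was tested directly. Camera called 19 lists, none of which held with an estimated correlation (adjusted p 0.311 to 0.662). Called more positive with anti-PD-1 were T cells (20 of 20, median 1.02), cytotoxic lymphocytes (19 of 19, 1.05, Gzmk at 1.99), inhibitory receptors (0.92), mast cells (0.98), MHC class II (0.83), MHC class I (0.41), interferon-gamma response (0.35), regulatory T cells (0.53), type 1 dendritic cells (0.45), NK cells (0.74), hypoxia (0.46) and cAMP targets (0.17). Called more negative were pericytes (-0.78, Notch3 at -1.41, SE 0.44; 2 lower when adjusted over the list alone), endothelium (-0.34), proliferation (-0.18), fibroblasts (-0.33), cholesterol synthesis (-0.22), muscle (-3.33) and skin (-1.78, 2 lower when adjusted over the list alone). Without vehicle replicate 8 (hypoxia 8.29, next 6.64), the interaction of list means went from 0.35 to 0.09 for hypoxia (0.21 without combination replicate 15) and from -0.46 to -0.26 for endothelium. Without celecoxib replicate 3 (skin 6.52, next 3.10), skin went from -0.60 to -0.01, cholesterol synthesis from -0.26 to -0.17 and muscle from -1.19 to -0.41, with muscle at -0.30 without celecoxib replicate 1. Proliferation went from -0.22 to -0.12 without combination replicate 14. EdgeR called 0 genes (413 at an unadjusted p under 0.05), limma-voom 1 and DESeq2 2. Without any one of anti-PD-1 replicates 12 and 14 or combination replicates 2, 10 and 11, edgeR called 1 gene.

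Under anti-PD-1, camera called 12 lists between R and NR tumours, none of which held with an estimated correlation (adjusted p 0.581 to 0.829). For hypoxia and glycolysis all 24 members were positive (median 1.18), with the glycolytic genes Aldoa at 1.33 (SE 0.40) and Tpi1 at 0.97 (SE 0.28), and 22 rose when adjusted over the list alone against 0 over all genes. The list averaged 6.64 ± 1.33 log2 CPM in 4 R and 5.64 ± 0.68 in 13 NR tumours (exact permutation p = 0.0466, adjusted p 0.552), above the NR median in 3 of 4. Replicates 12 and 14, at 7.41 and 8.12, stood apart from replicates 15 and 17, at 5.67 and 5.37, and their T cell list means were 1.10 and -0.70, against 2.36 and 3.11 in the other pair. Ptgs2 stood at 1.45 (SE 0.59, adjusted p 0.734). EdgeR called 0 of 14247 genes with 923 at an unadjusted p under 0.05; limma-voom and DESeq2 called 0 each. Also called up were immediate early genes (median 0.38, Ier3 at 1.58), interferon-gamma response (34 of 34, 0.57) and muscle (0.42). Down were proliferation (-0.30), macrophages (-0.45, Mrc1 at -0.82), red blood cells (-1.07), mast cells (-0.34), B cells (-0.59), mature dendritic cells (-0.33) and T cells (-0.24). Type I interferon was called down on a positive median and mean (both 0.07). Each of the 12 differences of list means moved by over 1.5 times without at least 1 tumour. Without replicate 14, the hypoxia difference was 0.51 (from 6.64 against 5.64 with all tumours), macrophages went from -0.61 to -0.30 and mast cells from -0.93 to -0.09, and T cells (-0.49 to 0.23) and type I interferon (-0.29 to 0.19) turned. Without replicate 12, proliferation went from -0.26 to -0.11 and red blood cells from -1.24 to -0.81. Interferon-gamma went from 0.45 to 0.07 without replicate 17 and to 1.13 without replicate 14.

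Under the combination, camera called tumour-promoting inflammation up in R against NR tumours, with an estimated-correlation adjusted p of 0.0815 and a fry adjusted p of 0.0291. The list was positive in 13 of 14 members (median 0.99), with Cxcl1 at 1.95 (SE 0.49, adjusted p 0.329) and Cxcl2 at 2.20 (SE 0.78), while the gelatinase Mmp9 was negative (-1.11, SE 0.31); 3 rose and 1 fell when adjusted over the list alone. It averaged 3.74 ± 0.51 log2 CPM in 12 R and 2.95 ± 0.39 in 4 NR tumours, above the NR median in 12 of 12 (exact permutation p = 0.0154, adjusted p 0.19). Libraries with other tissue were 4 of these R and 0 of these NR tumours. Among them were R replicates 14 and 13, with the highest inflammation means, 4.76 and 4.65. Presence of other tissue is thus partly confounded with the label here. The R tumours without other tissue had inflammation means from 3.11 (replicate 11) to 3.88 (replicate 8). The NR tumours ranged from 2.43 to 3.36. NR replicate 2 had a muscle list mean of 2.87, just under the limit of 3 chosen after the data were examined. Nos2, the inducible nitric oxide synthase of the interferon-gamma list, stood at 4.38 (SE 1.07), and 34 of 34 members of that list were positive (median 0.86, 1 rising when adjusted over the list alone, estimated-correlation adjusted p 0.351). EdgeR called 0 genes, with 1298 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 17; edgeR called 2 without combination replicate 12.

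The other 17 list calls were lost with an estimated correlation (adjusted p 0.273 to 0.49). Cytotoxic lymphocytes (19 of 19, median 1.64, Gzmb at 2.21, SE 0.79) and T cells (20 of 20, 1.38) were called up in these R tumours, with hypoxia (0.96), inhibitory receptors (1.27, 2 rising when adjusted over the list alone), MHC class II (1.08), MHC class I (0.53), NK cells (0.96, 2), neutrophils (1.06, 6 rising and 1 falling), NF-kB targets (0.45), immediate early genes (0.75, 1), type 1 dendritic cells (0.84), regulatory T cells (0.56), muscle (3.26) and adipocytes (2.62). Proliferation (-0.33, Birc5 at -0.58), cholesterol synthesis (-0.40, Insig1 at -1.35, 1 falling when adjusted over the list alone) and mitochondrially encoded transcripts (-0.39, 2 falling) were down. Without combination replicate 6, differences of list means went from 1.15 to 0.69 for cytotoxic lymphocytes, 0.91 to 0.58 for interferon-gamma, 1.12 to 0.73 for inhibitory receptors and 0.70 to 0.40 for NK cells.

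In the interaction of response label and treatment, camera called 21 lists, none of which held with an estimated correlation (adjusted p 0.39 to 0.685). T cells (20 of 20, median 1.52) and cytotoxic lymphocytes (19 of 19, 1.40) were called up, that is, more positive in R against NR under the combination. Up with them were type I interferon (0.17), macrophages (0.80), inhibitory receptors (1.17), type 1 (0.99), mature (0.58) and plasmacytoid (0.98) dendritic cells, adipocytes (2.42), NK cells (1.01), MHC class II (1.35), mast cells (0.85), neutrophils (0.76), NF-kB targets (0.42), interferon-gamma response (0.19), muscle (2.80), regulatory T cells (0.42), monocytes (0.24), inflammation (0.59) and B cells (0.84); cholesterol synthesis was down (-0.36). Only 9 lists were called without anti-PD-1 replicate 14, an R tumour whose T cell list mean was -0.70 log2 CPM. Without it 18 of the 21 interactions of list means moved by over 1.5 times: T cells went from 1.41 to 0.69 and cytotoxic lymphocytes from 1.65 to 0.85, and interferon-gamma (0.46 to -0.22) and regulatory T cells (0.49 to -0.02) turned. Inflammation went from 0.41 to 0.21 without anti-PD-1 replicate 17 and to 0.24 without combination replicate 5. EdgeR called 0 genes (329 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 2.

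Among NR tumours, 4 genes separated the combination from anti-PD-1: Dbp rose by 2.53 (SE 0.37, edgeR adjusted p 0.000201), from 13.6 ± 6.47 to 79.3 ± 58.5 CPM (n = 13 and 4), with Tef (1.70), Per3 (1.15) and Nr1d2 (0.96). The count was 1 without combination replicate 5 or 6 and 7 without replicate 12, and 816 genes had an unadjusted p under 0.05; DESeq2 called 13, and edgeR 1 with the clock covariate. Camera called 7 lists, none of which held with an estimated correlation (adjusted p 0.176 to 0.942), and 12 without combination replicate 2 or 6. Mitochondrially encoded transcripts were up (7 of 7, median 0.56, 3 rising when adjusted over the list alone). Tumour-promoting inflammation (2 of 14 positive, median -0.83, Il1b at -0.89), neutrophils (-0.57), adipocytes (-2.27), hypoxia (-0.62), pericytes (-0.48) and endothelium (-0.30) were down. Among R tumours edgeR called 0 genes (1051 at an unadjusted p under 0.05; limma-voom 0, DESeq2 0), and 4 with the clock covariate.

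Also among R tumours, camera called 21 lists, none of which held with an estimated correlation (adjusted p 0.357 to 0.468), and only 6 without anti-PD-1 replicate 14. Cytotoxic lymphocytes (19 of 19, median 1.33, Klrc1 at 3.16, 5 rising when adjusted over the list alone) and T cells (20 of 20, 1.36) were called up with the combination. Macrophages (0.81), mast cells (1.15, 1), NK cells (1.03), interferon-gamma response (0.34), type 1 (0.82) and plasmacytoid (0.72) dendritic cells, MHC class II (1.14), MHC class I (0.42), type I interferon (0.03), inhibitory receptors (1.02), NF-kB targets (0.33), B cells (1.16), regulatory T cells (0.55), mitochondrially encoded transcripts (0.24) and red blood cells (0.77, 2) were up. Hypoxia (-0.75), fibroblasts (-0.31), cholesterol synthesis (-0.26) and unfolded protein genes (-0.26) were down. Without anti-PD-1 replicate 14, 19 of the 21 differences of list means moved by over 1.5 times: cytotoxic lymphocytes went from 1.85 to 1.05, T cells from 1.51 to 0.78 and hypoxia from -0.67 to -0.17. Interferon-gamma (0.59 to -0.09), type I interferon (0.40 to -0.08) and MHC class I (0.36 to -0.04) turned without it.

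Of the 18 panel genes, 17 were tested and none passed in any of the 11 comparisons; Il6, below the expression filter, averaged 0.205 ± 0.335 CPM with vehicle. For the combination against anti-PD-1 the log2 changes included Prf1 1.90, Cd8a 1.55, Pdcd1 1.33, Cd274 1.27, Gzmb 1.13, Ifng 1.02, Cxcl9 0.70, Cxcl1 0.67, Ncr1 0.46, Foxp3 0.44, S100a8 0.40, Cxcl2 0.21, Ptgs2 0.19, Cxcl10 0.19, Arg1 -0.10 and Il1b -0.37. Cd8a measured 20.8 ± 21.97 CPM with the combination and 7.21 ± 12.6 with anti-PD-1.

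The inflammation and cytotoxic lists were compared across tumours within 4 groups. In 9 vehicle tumours Pearson's r was -0.688 (exact permutation p = 0.0406, adjusted 0.162) and Spearman's rho -0.517 (exact p = 0.162), and r became -0.037 without the 2 tumours farthest from the median, so the relation rests on those tumours. In 7 celecoxib tumours r was 0.161 (exact p = 0.727) and rho 0.25 (exact p = 0.595), and r without 2 was 0.025. In 13 anti-PD-1 NR tumours r was 0.374 (permutation p = 0.202) and rho 0.473 (p = 0.105), with r of 0.633 without 2, and in 12 combination R tumours r was 0.029 (permutation p = 0.928) and rho -0.042 (p = 0.904), with r of -0.392 without 2. After regression on the muscle list, r in the combination R tumours was 0.507 (permutation p = 0.0921, adjusted p 0.184).

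**Figure D3:**
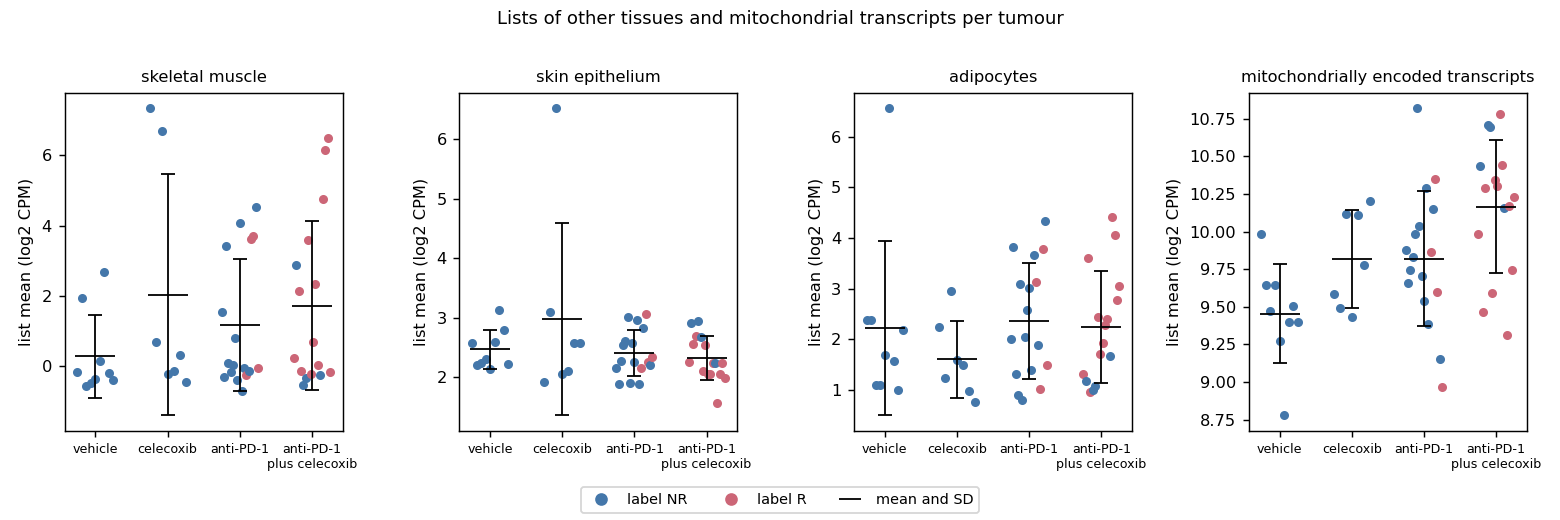
Each point is a tumour, coloured by response label, with the mean log2 CPM of the muscle, skin, adipocyte and mitochondrially encoded lists on the vertical axes and treatment groups along the horizontal axes; bars are mean and SD. Celecoxib replicates 1 and 3 stand at 7.35 and 6.70 for muscle, and mitochondrial transcripts average 10.17 with the combination against 9.46 with vehicle.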

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

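The tests of the clock and muscle patterns were chosen after their results were seen. The mitochondrial tests and the splits of the samples were set before. The limits for libraries with other tissue, which the other-tissue test of the mitochondrial list uses, were chosen after the data were examined. Samples far from the others of their group were sought in groups of 4 to 10 tumours by Dixon's ratio over 224 group and measure pairs: 20 passed, where chance gives about 11.2. The measures overlap, so these are not independent.

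Vehicle replicate 8 stood alone on 11 measures. Its means were low for the prostaglandin pathway (3.08), type I interferon (5.15), regulatory T cells (0.81), mature dendritic cells (2.48), macrophages (5.09), monocytes (3.23), mast cells (1.08) and endothelium (1.69), and high for hypoxia and glycolysis (8.29, next 6.64). Ptgs2 was high in it (5.95 log2(CPM + 1), next 4.12) and Ncr1 low (1.86). Vehicle replicate 5 was low for TGF-beta targets (3.69), vehicle replicate 6 high for adipocytes (6.56, next 2.39) and vehicle replicate 1 high for Il6 (1.02). Celecoxib replicate 3 was high for cholesterol synthesis (5.60) and skin (6.52, next 3.10) and low for Cxcl1 (2.11), and celecoxib replicate 4 was high for Cxcl10 (8.50). Among the combination NR tumours, replicate 12 was high for cholesterol synthesis (5.33) and replicate 2 for muscle (2.87). By the camera test of the difference itself, 19 lists differed in their celecoxib effect with and without anti-PD-1, and 21 in their R against NR effect between the treatments; none held with an estimated correlation.

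Dbp, Per2, Per3, Tef, Nr1d2 and Cry2 were lower with anti-PD-1 than with vehicle and Arntl higher; they are called the clock genes here, a grouping made after the data were seen. The tables argue against fewer leukocytes as the whole cause, because the mean of the 6 lower genes minus Arntl differed by -2.71 before and -2.796 after adjustment for the T cell, macrophage and cytotoxic lists. The genes were picked from this comparison, so no p is given for that difference. For 6 of the 7 genes they argue against anti-PD-1 moving them whatever else is given, as the only cause, because edgeR called these 6 in the opposite direction in the combination against anti-PD-1, adjusted over all genes. Both comparisons share the anti-PD-1 tumours. For Cry2 this stays open (0.349, edgeR adjusted p 0.231). Collection at another time of day may explain the pattern: the median change of the 4 tested opposite-phase genes was 0.588. Arntl, 1 of these 4, is itself among the called genes, so the median in part restates the pattern. Clock, Nfil3 and Cry1 did not pass, Cry1 went the other way, and Npas2 was not tested. Collection time is not in the labels and would be confounded with treatment, so it cannot be told apart from an effect of anti-PD-1 without celecoxib.

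Muscle genes were higher with celecoxib than with vehicle. Celecoxib as a direct cause is argued against, because only 2 of 7 celecoxib tumours lay over 1 log2 unit above the vehicle median. A piece of muscle in some samples is a candidate explanation, but its test met neither bound set for it: without the libraries with other tissue the list median was -1.745, neither within 1 log2 unit of 0 nor above 1. The sign change leaves that test undecided. Vehicle replicates 2 and 7, with muscle list means of 1.94 and 2.68, lay under the limit of 3 and were kept. The highest celecoxib tumour kept was replicate 2, at 0.67.

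Mitochondrially encoded transcripts were higher with the combination than with vehicle. Other tissue is argued against, because the difference was 0.78 without the libraries with other tissue (exact permutation p = 0.000159). Library size is argued against, because it was 0.689 after the log2 library total (exact permutation of residuals, p = 0.000576). Both p-values come from the tumours in which the list was called and are not adjusted over lists. They are therefore no further evidence that the list differs. RNA quality and handling were not tested, so an effect of treatment remains 1 of several open hypotheses.

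For each comparison 50 splits of the same libraries, the real one included, were fitted. Counts as large as the real 69 for the combination against anti-PD-1 came from 2 splits (highest other 85), and as large as the real 4 among NR from 1 (highest other 0). Both shares were under 0.05, but they were not adjusted over the comparisons. With 50 splits no share can be under 1 in 50, so chance is not excluded. The share was over 0.05 for anti-PD-1 against vehicle (real 12, reached by 3 splits, highest other 78). It was also over 0.05 for the combination against vehicle (real 10, by 6, highest other 487) and against celecoxib (real 5, by 6, highest other 24). For anti-PD-1 against vehicle the splits were scored on the count, and none was scored on the clock genes alone. Dbp had an edgeR adjusted p of 2.13e-07 over all genes. Of the 12 genes, 8 were called in all 26 fits without 1 library, with Fkbp5 and Spon2 among them but not Cry2. Such fits do not test chance. The clock measure did not overlap (2.57 to 4.25 with vehicle, -0.66 to 1.72 with anti-PD-1). It is built from genes called in this comparison, so its separation is not further evidence. For the 6 comparisons with a real count of 0, all 50 splits were as large. Any split reaches a count of 0, so this decides nothing. The highest other count was 18 for celecoxib against vehicle, 66 for the celecoxib interaction and 0 for R against NR under anti-PD-1. It was 456 for R against NR under the combination, 243 for the response interaction and 2626 for the combination against anti-PD-1 among R. Splits calling many more genes than the real grouping may point to a structure of the samples. What drives them was not tested.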

How the results depend on the processing

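Leaving out each library of the 4 treatments, removing the libraries with other tissue, the clock covariate, the permutation of list means and the list means without each library were chosen after the data were examined; the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers, and the numbers used here only name tumours. Barnard's exact test gave a p of 0.00456 for the share of R tumours. RLE normalization left every gene count of the 11 comparisons within 1.5 times its reported value. Unless a reason is given, the cause was not tested.

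DESeq2 called 7 genes for celecoxib against vehicle, 22 for anti-PD-1 against vehicle, 67 for the combination against vehicle, 297 for the combination against anti-PD-1, 2 for the combination against celecoxib, 2 for the celecoxib interaction, 17 for R against NR under the combination, 2 for the response interaction and 13 for the combination against anti-PD-1 among NR. Dsp and Sbsn reversed there for the combination against celecoxib (1.63 and 0.39). Limma-voom called 3 genes for the combination against vehicle, 33 against anti-PD-1, 0 against celecoxib and 1 for the celecoxib interaction. Without a filter on low counts, 49 genes were called for celecoxib against vehicle, 24 for anti-PD-1 against vehicle, 22 for the combination against anti-PD-1 and 124 against celecoxib. With the compared groups alone, the combination had 2 calls against vehicle, 19 against anti-PD-1 and 1 against celecoxib, from fewer samples.

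With the muscle list as covariate, the combination had 63 calls against vehicle, 153 against anti-PD-1 and 2 against celecoxib. Without the libraries with other tissue it had 787 (437 higher and 350 lower), 11 and 0, and Sbsn reversed against celecoxib (0.39). These fits had fewer samples, and what drove the rise to 787 was not tested. Lists called were then 4 for celecoxib against vehicle, 11 for the combination against celecoxib, 6 for R against NR under anti-PD-1 and 10 for the response interaction. With the clock measure as covariate, anti-PD-1 against vehicle had 0 calls, and the combination 2 against vehicle, 0 against anti-PD-1, 0 against celecoxib, 1 against anti-PD-1 among NR and 4 among R, with 11 lists against celecoxib. That covariate is built from genes called for anti-PD-1 against vehicle and the combination against anti-PD-1, so losing those genes there follows from its construction; the losses against vehicle and celecoxib were not explained. Arntl reversed for anti-PD-1 against vehicle (-0.41), Arntl (0.12) and Tef (-0.11) for the combination against anti-PD-1, and Tef among NR (-0.038). There were 47 calls of genes named for their fold change or picked after the data were seen. A gene called in several comparisons counts once for each. Of these calls, 18 held under all alternatives considered here but the clock covariate, which left 2. Leaving out each library of the 4 treatments in turn was not among these alternatives. DESeq2 kept 43, RLE 46, the muscle covariate 44, no filter 33, limma-voom 28, the compared groups alone 27 and removal of other tissue 30.

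With an estimated correlation 0 lists were called in each of the 11 comparisons, against 7 to 21 with the preset value, since members of a list moved together between tumours (estimated correlation 0.034 to 0.869 among the called lists). Fry called 0 lists except 1 for the combination against vehicle and 1 for R against NR under the combination. Permutation of list means called 0 in the comparisons it covered, except 1 for the combination against vehicle.

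Leaving out 1 library gave 0 genes throughout for celecoxib against vehicle, 8 to 17 for anti-PD-1 against vehicle, 2 to 157 for the combination against vehicle, 13 to 449 against anti-PD-1, 0 to 7 against celecoxib and 0 to 1 for the celecoxib interaction. For the 5 comparisons with response labels only tumours of the groups of 4 (anti-PD-1 R and combination NR) were left out, not the 13 anti-PD-1 NR and 12 combination R tumours. This gave 0 genes for R against NR under anti-PD-1, 0 to 2 under the combination, 0 for the response interaction, 1 to 7 among NR and 0 among R. With the same tumours left out, lists ranged from 10 to 18 for R against NR under anti-PD-1, 17 to 21 under the combination, 9 to 22 for the response interaction, 5 to 12 among NR and 6 to 23 among R. In the simulated data edgeR recovered 51% of changes of 1 log2 unit and 79% of changes of 2 for 4 R against 13 NR tumours; 12 R against 4 NR were not simulated.

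Differences of list means without 1 library turned in 9 called lists. The ranges were -0.01 to 0.28 for endothelium and -0.08 to 0.69 for skin (celecoxib against vehicle), -0.74 to 0.19 for type I interferon and -1.03 to 0.23 for T cells (R against NR under anti-PD-1), and -0.22 to 0.84 for interferon-gamma and -0.02 to 0.83 for regulatory T cells (response interaction). Among R they were -0.09 to 0.97 for interferon-gamma, -0.08 to 0.85 for type I interferon and -0.04 to 0.54 for MHC class I.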

Other observations

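These values were looked at after the data were examined. The 4 lowest T cell list means were -0.70 log2 CPM in anti-PD-1 replicate 14 (R), -0.08 in combination replicate 15 (R), 0.72 in vehicle replicate 8 (NR) and 0.85 in anti-PD-1 replicate 3 (NR). Their hypoxia and glycolysis means were 8.12, 7.89, 8.29 and 6.18. The next 4 T cell means were 1.10, 1.14, 1.34 and 1.36, in anti-PD-1 replicates 12, 5, 10 and 7. Hypoxia and glycolysis means there were 7.41, 5.41, 5.15 and 4.98, so low T cell means did not always go with high hypoxia means. The relation over all tumours was not tested. The clock measure correlated within anti-PD-1 tumours with the last number of the sample titles (n = 17, Pearson's r 0.54, permutation p = 0.0243, adjusted p 0.0972; Spearman's rho 0.559, p = 0.0217; r 0.466 without the 2 farthest tumours). The other 3 groups gave r of 0.095 with vehicle (n = 9, exact permutation p = 0.818), -0.758 with celecoxib (n = 7, exact permutation p = 0.0542, adjusted p 0.108) and 0.155 with the combination (n = 16, permutation p = 0.564). With celecoxib, Spearman's rho was -0.857 (exact permutation p = 0.0238) and r was -0.59 without the 2 farthest tumours, the opposite sign to anti-PD-1. The numbers run in separate blocks: 1 to 10 with vehicle, 11 to 20 with celecoxib, 21 to 44 with anti-PD-1 and 45 to 63 with the combination. What the title numbers stand for is not given in the sources used here. Between groups, any order they follow cannot be told apart from treatment. Within the combination, the clock measure was 1.51 to 2.63 for numbers 45 to 49. It was 3.26 to 5.03 for numbers 50 to 54 and 2.20 to 3.49 for numbers 55 to 63. A linear r does not describe such a pattern. These ranges of numbers were picked from the values and were not tested.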
